A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

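Total RNA from 21 libraries, 3 of each of 7 yeast strains in log-phase growth at 30 °C in a rich medium, was depleted of ribosomal RNA and sequenced as stranded pairs of 50-base reads. Per the labels, the authors trimmed reads with cutadapt 1.16, aligned them to the R64 (sacCer3) genome with STAR 2.6.1b, counted them with featureCounts 1.6.3 of the Subread package and compared strains with DESeq2 1.22.2 and the hciR package. The deposited counts are raw read counts per gene and library in a pair of tables. In the full-gene table the authors counted all signal within a gene, and in the mid-gene table they counted sense reads over the middle 70% of a gene, the feature they used for their own main comparisons. The authors' deposited comparison table holds log2 fold changes, and the deposited p-value columns used here hold adjusted p-values from DESeq2, for each mutant against WT and each kind of count.

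The full-gene table held 5823 genes and that of mid-gene counts 5894, of which 5810 were in both, 84 only in the mid-gene table and 13 only in the full-gene table; 5623 identifiers matched the R64 annotation, from which coordinates were taken. Full-gene totals ran from 4860861 to 7803152 and mid-gene totals from 5464008 to 7657746 per library. No pair of libraries was identical. Mid-gene counts were not nested in the full-gene counts: 307 genes had more mid-gene than full-gene counts, among them TEF1 (4.02 times), TEF2 (5.47 times), EFT2 (5.16 times) and HXT6 (4.97 times), all with near-identical relatives, while the median ratio was 0.886. How reads that match several places or overlapping genes were counted is not stated, and why these genes differ between the tables was not tested, so values of genes with near-identical copies are uncertain.

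Strains were compared on full-gene counts with edgeR 4.0.16 in R 4.3.3, using filterByExpr (5618 genes kept, 205 left out), TMM scaling and the quasi-likelihood test. All 21 libraries entered 1 model with strain as its only term, and genes with a Benjamini-Hochberg false discovery rate under 0.05 were called. The contrasts were each mutant against WT, the double mutant against the sum of its singles on the log2 scale for each protein, and spt6-R,KK against rpb1-TPY,FSP. The common biological coefficient of variation was 0.154. Errors of log2 fold changes are standard errors of the edgeR contrasts, and errors of CPM are standard deviations over 3 libraries.

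Gene lists were tested with camera on the same model with an inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison, with the correlation estimated from the data and with fry beside it (limma 3.58.1). The 33 lists were histones, elongation factors and histone chaperones, RNA polymerase II subunits, the phosphate regulon, genes controlled by upstream transcription or start-site choice, heat shock and chaperones, general stress genes, cytosolic ribosomal proteins, ribosome biogenesis, glucose-repressed carbon metabolism, hexose transporters, glycolysis and fermentation, amino acid synthesis, methionine and sulfur assimilation, the iron regulon, NAD synthesis, thiamine synthesis, a-specific genes, alpha-specific genes, pheromone-induced genes, meiosis and sporulation, the DNA damage response, cyclins, daughter-cell separation, cell wall proteins, flocculins, the PAU and COS families, small nucleolar and nuclear RNAs, oxidative phosphorylation, ergosterol synthesis, the proteasome, auxotrophy and strain markers, and genes with known cryptic internal promoters. Camera on the interactions and on the double mutants against each other was added after the data were seen.

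The mid-gene share was tested with limma (trend and robust settings) on log2 CPM of mid-gene minus full-gene counts, with a pseudocount of 1 and a mean of at least 20 counts, after each library's median difference was set to 0. A ratio of nested counts had been preferred, and this difference was the stated fallback. The median centring was not in the fallback as written; it was added after a test on simulated data and departs from the design.

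The choice of comparisons, main test, lists, named genes and most alternatives was made before the data were examined. By that rule SPT6 and RPO21 are named in every strain. Per double mutant the 10 largest rises and 10 largest falls are named among called genes with a mean count of at least 20 in 1 of the strains and no overlap in CPM between the 3 mutant and 3 WT libraries. For single mutants the top 3 each way are named, for the interactions (without the overlap condition) and the double mutants against each other the top 5, and for the mid-gene share the top 2. Per list called in a double mutant up to 4 called members with the largest changes are named, and any measured member of the histone, phosphate, start-site, NAD, a-specific, alpha-specific and marker lists can be. Other genes named, among them PCA1, STE11 and BPL1 against WT, and values in strains where the rule did not pick the gene, were chosen after their values were seen. A fold against a group with 0 counts is given as a lower bound from 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% interval; both cover counting error only.

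Similarity of mutants was measured across genes beside 20 simulated series with unchanged groups. In each series all libraries, WT included, were drawn anew and independently, and all mutants shared the simulated WT group. On simulated data shaped like these counts, edgeR recovered 42.5% of 80 genes changed 1.5-fold, 94.7% of 57 changed 2-fold and 98.4% of 63 changed 4-fold, with 3.51% of 228 calls false and 0 calls where nothing was changed. Camera called 2 lists where 1 of 32 was changed. The mid-gene test recovered all of 200 genes changed 2-fold, with 7.83% of 217 calls false. Its simulated mid-gene counts were drawn out of the simulated full-gene counts and so were nested, unlike the real ones. These shares therefore need not hold for the real test.

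Alternatives were size factors by median of ratios, no filter, at least 50 counts in 3 libraries, mid-gene counts, replicate number as a block, only the compared strains, DESeq2 1.42.0, leaving out each library, an estimated correlation or fry for lists, and a pseudocount of 5 or a minimum of 100 for the mid-gene share. Robust edgeR estimation, both double-mutant libraries numbered 1 left out together, and no median centring were added after the data were seen. Raw reads were not used here.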

Results

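RNA was sequenced from 21 samples of budding yeast (Saccharomyces cerevisiae), 3 libraries for each of 7 strains. Spt6 is a histone chaperone and transcription elongation factor that travels with RNA polymerase II, and its tandem SH2 domain binds the linker between the body and the C-terminal repeats of Rpb1, the largest polymerase subunit. The strains were a wild type (WT), the SPT6 mutants spt6-R, spt6-KK and their combination spt6-R,KK, and the RPB1 mutants rpb1-TPY, rpb1-FSP and their combination rpb1-TPY,FSP. The labels do not spell out the residues behind these names. All strains were in log-phase growth at 30 °C in a rich medium. The labels do not say that the 3 libraries of a strain came from separate cultures, so the p-values measure only the spread between these samples. Counts per full gene summed to between 4860861 (WT library 3) and 7803152 (rpb1-TPY,FSP library 1) per library, and 5618 genes had enough counts to be tested. The biological coefficient of variation between libraries of a strain was 0.154.

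The principal component that carried 42.2% of the variance separated 3 sets of strains, within which strains overlapped or lay close. The WT libraries lay between -24.4 and -19.0 on it and the rpb1-TPY libraries between -22.6 and -15.0. Libraries of spt6-R, spt6-KK and rpb1-FSP lay between -6.83 and 0.20, and those of both double mutants between 18.8 and 29.1. The next component carried 11.4%. Ribosomal RNA took 7.10%, 12.6% and 19.1% of the mid-gene sense counts in WT libraries 1, 2 and 3, against 2.98% to 6.21% in the mutant libraries. It took 1.30% to 2.46% of the full-gene counts in every library. RDN18-1, RDN25-1, RDN37-1 and RDN58-1 were counted only over mid-gene regions, so these shares cover different genes and cannot be compared.

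SPT6 (YGR116W, R64/sacCer3 chromosome VII 720409 to 724764) was itself lower in strains that carry the R change. Its mean was 266 ± 30.1 CPM (counts scaled to library size; SD, n = 3) in WT, 143 ± 6.60 in spt6-R and 130 ± 9.15 in spt6-R,KK. The log2 fold change was -0.89 ± 0.16 (SE; edgeR adjusted p = 0.00245) in spt6-R and -1.03 ± 0.16 (adjusted p = 4.59e-05) in spt6-R,KK. In rpb1-TPY,FSP SPT6 fell by 0.45 ± 0.16 (adjusted p = 0.0328), to 195 ± 34.6 CPM, a call that was lost without WT library 2 (adjusted p = 0.0977) or 3 (0.108) or rpb1-TPY,FSP library 2 (0.114) or 3 (0.0722). It did not pass in spt6-KK (-0.48 ± 0.16, adjusted p = 0.0513), in rpb1-TPY (-0.06, adjusted p = 1) or in rpb1-FSP (-0.12, adjusted p = 0.785). The difference between the double mutants (-0.58 ± 0.16, adjusted p = 0.872) did not pass either. RPO21 (YDL140C, chromosome IV 205360 to 210561), which encodes Rpb1, had 537 ± 9.56 CPM in WT and passed in no strain. Its log2 fold changes ran from -0.26 in spt6-KK (adjusted p = 0.174) over -0.17 in rpb1-TPY, -0.08 in rpb1-TPY,FSP, -0.04 in spt6-R,KK and -0.01 in rpb1-FSP to 0.09 in spt6-R (adjusted p = 0.71), each with an SE of 0.13.

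**Figure D1:**
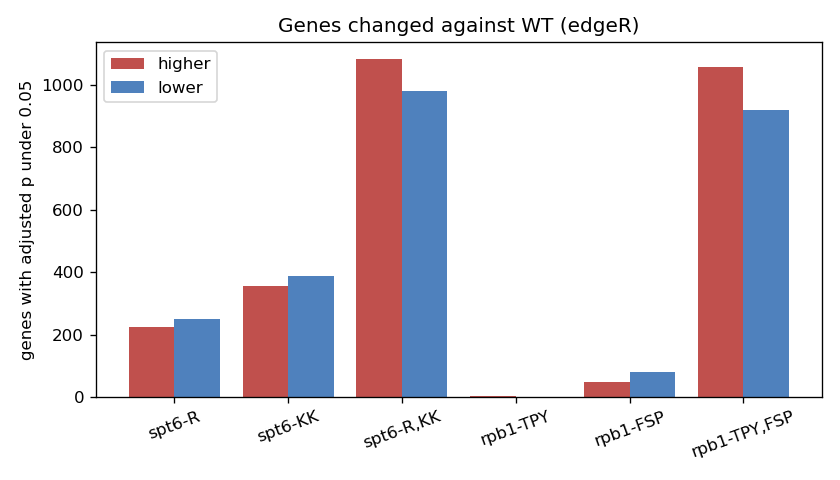
Genes with a changed full-gene count (edgeR, false discovery rate under 0.05) in each mutant against WT, as bars from 0, with genes that rose and fell drawn apart, 3 libraries per strain. The double mutants changed 2064 and 1978 genes and rpb1-TPY changed 3.

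The comparison of spt6-R,KK with WT asks what the combined change on the Spt6 side does to transcript levels. Ribosomal protein genes fell in 135 of 138 cases and ribosome biogenesis genes in 35 of 43, while 22 of 29 general stress genes and 16 of 21 genes of glucose-repressed carbon metabolism rose. The list call held for ribosomal proteins (adjusted p = 0.0319 with an estimated correlation) and was lost for the others (adjusted p = 0.354, 0.126 and 0.0866 with an estimated correlation). In all 2064 genes changed, 1082 up and 982 down, which is 36.7% of the genes tested. 429 rose and 151 fell by 2-fold or more. IMD2 (chromosome VIII 554396 to 555967), an IMP dehydrogenase gene whose expression depends on the choice of its transcription start site, rose from 39.0 ± 11.5 to 525 ± 18.7 CPM (log2 3.76 ± 0.18, adjusted p = 8.3e-12). FLO11 (chromosome IX 389572 to 393675), a cell-surface flocculin gene, fell from 335 ± 125 to 17.9 ± 6.09 CPM (log2 -4.23 ± 0.33, adjusted p = 1.15e-08). By mid-gene counts its log2 fold change was -2.43, so the size of this fall is uncertain.

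In spt6-R,KK the tryptophan synthesis gene TRP1 (chromosome IV 461842 to 462516), a common strain marker, rose most by fitted value (log2 5.24 ± 0.24, adjusted p = 8.3e-12), from 0.74 ± 0.15 CPM in WT to 29.0 CPM. TRP1 had 3 to 12 counts per library in WT and rpb1-TPY,FSP and 91 to 191 in the other strains. The labels do not give the TRP1 genotype of any strain, so a difference in strain markers stays open for every TRP1 value given here. UTR5 had 78 counts against 2 in WT, a ratio of 36.3 with a 95% exact counting interval of 9.71 to 305. The cell wall mannoprotein gene HPF1 (chromosome XV 28703 to 31606) rose by 4.20 ± 0.27 (adjusted p = 1.32e-09) and its relative YIL169C by 4.78 ± 0.46 (adjusted p = 1.43e-07). These near copies share sequence, so reads of one can be counted in the other. Next in size were YER085C (4.02 ± 0.62), HRA1 (3.88 ± 1.02), AZR1 (3.76 ± 0.80), FYV12 (3.69 ± 0.59) and RTC2 (3.67 ± 0.99). HRA1 had 48, 12 and 9 counts and RTC2 625, 90 and 45 counts in spt6-R,KK libraries 1, 2 and 3, and without library 1 RTC2 was no longer called (1.79, adjusted p = 0.133). Below FLO11, the largest falls were in PWR1 (-3.83 ± 0.55), the pseudohyphal growth gene SFG1 (-2.06 ± 0.42), RPL36A (-1.95 ± 0.14), SPS4 (-1.91 ± 0.60), RPL27B (-1.86 ± 0.12), RPL26A (-1.86 ± 0.15), the fatty acid activation gene FAA3 (-1.75 ± 0.16), RPS23A (-1.72 ± 0.13) and COA4 (-1.70 ± 0.36). SPS4 lost its call without WT library 2 (adjusted p = 0.0571) or spt6-R,KK library 1 (0.051).

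Of the 138 cytosolic ribosomal protein genes, 135 fell and none rose in spt6-R,KK (135 adjusted over the list alone), with a median log2 fold change of -1.03 and a camera adjusted p of 6.25e-90. RPL36A fell from 274 ± 13.4 to 70.9 ± 9.60 CPM. The call held at adjusted p = 0.0319 with an estimated correlation, and at 0.0449 without the libraries numbered 1 of both double mutants. Ribosome biogenesis genes fell in 35 of 43 cases (37 adjusted over the list alone; median -0.56, camera adjusted p = 2.67e-10, adjusted p = 0.354 with an estimated correlation). They included the snoRNP genes NOP58 (-1.10 ± 0.12), NOP1 (-1.04 ± 0.14), CBF5 (-1.03) and GAR1 (-1.01). Of 11 RNA polymerase II subunit genes other than RPO21, 8 fell (9 adjusted over the list alone; median -0.49, camera adjusted p = 0.00308, adjusted p = 0.126 with an estimated correlation), with RPO26 at -0.93 ± 0.15 and RPB8 at -0.82 ± 0.11, both shared with the other polymerases. Of 10 histone genes 7 fell (7 adjusted over the list alone; median -0.57, camera adjusted p = 0.00253, adjusted p = 0.452 with an estimated correlation), among them HTA1 (-0.89 ± 0.15), HHF2 (-0.83 ± 0.13), HTA2 (-0.82 ± 0.17) and HHT1 (-0.69 ± 0.14). The histone gene copies share reads. In glycolysis and fermentation 8 of 16 genes fell and 1 rose (9 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 0.0446, adjusted p = 0.717 with an estimated correlation), with ENO2 at -0.71, FBA1 at -0.69, PGK1 at -0.64 and the pyruvate decarboxylase gene PDC5 at 1.48 ± 0.21.

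Among the general stress genes, typical targets of Msn2 and Msn4, 22 of 29 rose in spt6-R,KK (24 adjusted over the list alone; median 1.12, camera adjusted p = 1.53e-11, adjusted p = 0.126 with an estimated correlation). Examples were SPI1 (3.02 ± 0.37), YGP1 (2.83), the glutamate decarboxylase gene GAD1 (2.78 ± 0.25) and the repressor gene XBP1 (2.77). Glucose-repressed carbon metabolism rose in 16 of 21 genes (18 adjusted over the list alone; median 1.64, camera adjusted p = 3.29e-07, adjusted p = 0.0866 with an estimated correlation), with GAL10 at 3.28 ± 0.51, the aldehyde dehydrogenase gene ALD4 at 2.70 ± 0.27 and the gluconeogenesis gene PCK1 at 2.12 ± 0.56, whose call was lost without spt6-R,KK library 2 (adjusted p = 0.0581). With an estimated correlation the list gained a call when the libraries numbered 1 of both double mutants were left out (camera adjusted p = 0.0276). ADH2, the alcohol dehydrogenase gene of ethanol use, had 3.34 ± 0.33 by full-gene counts but -0.16, without passing, by mid-gene sense counts. It shares long stretches with ADH1, so its rise is uncertain. Oxidative phosphorylation rose in 12 of 33 genes (13 adjusted over the list alone; median 0.37, camera adjusted p = 0.00261, adjusted p = 0.717 with an estimated correlation), led by the succinate dehydrogenase genes SDH2 (1.28 ± 0.21) and SDH4 (1.27).

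Of 5 genes controlled by upstream transcription or start-site choice, 3 rose in spt6-R,KK (4 adjusted over the list alone; median 1.33, camera adjusted p = 2.51e-07). Besides IMD2 these were SER3 (chromosome V 322686 to 324095), a serine synthesis gene repressed by transcription across its promoter, at 2.93 ± 0.29 (adjusted p = 1.97e-07) and the CTP synthase gene URA8 at 1.33 ± 0.15. URA2 (0.32, adjusted p = 0.0679) and ADE12 (-0.15, adjusted p = 0.75) did not pass. This call held at adjusted p = 0.0319 with an estimated correlation, but was lost in that test without the libraries numbered 1 of both double mutants (adjusted p = 0.055 with an estimated correlation). Of 5 genes with known cryptic internal promoters, PCA1 (0.81 ± 0.17) and STE11 (0.52 ± 0.20) rose and none fell (2 adjusted over the list alone; median 0.24, camera adjusted p = 0.378, fry adjusted p = 0.0194). fry asks whether the genes of a list move on balance one way and does not compare them with other genes.

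In the phosphate regulon 7 of 15 genes rose in spt6-R,KK (7 adjusted over the list alone; median 0.56, camera adjusted p = 0.00623, adjusted p = 0.0687 with an estimated correlation), led by the acid phosphatase genes PHO12 (3.63 ± 0.49), PHO11 (2.48 ± 0.29) and PHO5 (2.09 ± 0.36; chromosome II 429548 to 430951) and by PHM8 (2.25). PHO11 and PHO12 are near-identical copies. In the iron regulon 12 of 22 rose (14 and 1 down adjusted over the list alone; median 0.66, camera adjusted p = 0.000993, adjusted p = 0.514 with an estimated correlation), with the siderophore genes SIT1 (2.51 ± 0.31), FIT2 (2.46), ARN2 (1.99) and FIT3 (1.66). Thiamine synthesis rose in 9 of 17 genes (11 adjusted over the list alone; median 0.67, camera adjusted p = 0.000521, adjusted p = 0.126 with an estimated correlation). Its THI5 family members THI13 (2.69) and THI12 (2.66) share reads, and THI5 had 27 counts against 2 in WT (ratio 12.6, 95% exact counting interval 3.16 to 109). Without the libraries numbered 1 of both double mutants the medians were 0.333 for the phosphate and 0.415 for the iron regulon.

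In spt6-R,KK the PAU and COS families rose in 8 of 16 genes (12 adjusted over the list alone; median 0.74, camera adjusted p = 0.000742, adjusted p = 0.142 with an estimated correlation), for example PAU24 (3.12 ± 0.81), whose relatives share reads and whose call was lost without spt6-R,KK library 1 (adjusted p = 0.0576). Meiosis and sporulation genes rose in 9 of 25 cases and fell in 1 (9 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.0416, adjusted p = 0.408 with an estimated correlation), with DIT2 at 2.79 and ZIP2 at 2.67. DNA damage genes rose in 6 of 13 cases (6 adjusted over the list alone; median 0.36, camera adjusted p = 0.0148, adjusted p = 0.316 with an estimated correlation), with HUG1 at 1.94 ± 0.41 and RNR3 at 1.43. Cell wall genes rose in 11 of 23 cases (11 adjusted over the list alone; median 0.41, camera adjusted p = 0.00623, adjusted p = 0.562 with an estimated correlation), led by DAN1 (2.73; 1.70 and adjusted p = 0.0857 without spt6-R,KK library 1). All 3 tested alpha-specific genes rose (3 adjusted over the list alone; median 1.73, camera adjusted p = 0.0416, adjusted p = 0.142 with an estimated correlation), and 3 of 7 a-specific genes rose (3 adjusted over the list alone; median 0.78, camera adjusted p = 0.0433, adjusted p = 0.562 with an estimated correlation). The alpha-factor gene MF(ALPHA)2 (1.73) lost its call without WT library 1 (adjusted p = 0.126) or 3 (0.0956) or spt6-R,KK library 1 (0.0557) or 2 (0.0992). Without the libraries numbered 1 of both double mutants the a-specific list had a median of 0.406 and was not called (camera adjusted p = 0.168). The pheromone receptor gene of a cells, STE2, was at 637 CPM in WT and that of alpha cells, STE3, at 1.59 CPM. Of 7 auxotrophy and strain markers 3 rose (3 adjusted over the list alone; median 0.53, camera adjusted p = 0.00435, adjusted p = 0.243 with an estimated correlation), namely TRP1, LYS2 (1.48) and MET17 (0.99). Without spt6-R,KK library 1 LYS2 had 0.81 (adjusted p = 0.0198) and MET17 was not called (adjusted p = 0.0924). The list median was 0.175 without the libraries numbered 1 of both double mutants.

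The other lists were not called by camera in spt6-R,KK. Amino acid synthesis genes rose in 9 of 35 cases and fell in 1 (9 and 0 adjusted over the list alone; median 0.51, camera adjusted p = 0.0654), but the 3 libraries disagreed, with a mean per library of 0.29 ± 0.79 (SD). Of these genes 6 rose and 7 fell without the libraries numbered 1 of both double mutants (median -0.109, camera adjusted p = 0.452). With replicate number as a block camera did call the amino acid list, as given further below. Small nucleolar and nuclear RNAs rose in 10 and fell in 17 of 76 cases (camera adjusted p = 0.145; 10 and 17 adjusted over the list alone). With both libraries numbered 1 left out 9 rose and 27 fell, and the list was called downward (camera adjusted p = 0.0261, adjusted p = 0.769 with an estimated correlation). Methionine and sulfur genes rose in 8 and fell in 5 of 21 (0.376; 8 and 5 adjusted over the list alone), and elongation factors and histone chaperones rose in 1 and fell in 7 of 30 (0.074; 1 and 7 adjusted over the list alone). Heat shock genes rose in 1 and fell in 7 of 24 (0.376; 1 and 7 adjusted over the list alone), ergosterol genes rose in 5 and fell in 2 of 24 (0.81; 5 and 2 adjusted over the list alone), and pheromone-induced genes rose in 5 and fell in 3 of 20 (0.67; 5 and 3 adjusted over the list alone). NAD synthesis (1 up, 3 down of 11; 0.393; 1 and 3 adjusted over the list alone), proteasome (1 up, 3 down of 33; 0.429; 1 and 3), cyclins (1 up, 2 down of 13; 0.54; 1 and 2), daughter-cell separation (2 up, 2 down of 11; 0.782; 3 and 2), hexose transporters (1 up, 1 down of 8; 0.588; 0 and 0) and flocculins (1 up, 1 down of 6; 0.618; 1 and 1) followed. In that setting without the libraries numbered 1, NAD synthesis was called downward (1 up, 6 down; median -0.621, camera adjusted p = 0.0261, adjusted p = 0.305 with an estimated correlation), where 6 ergosterol genes and 5 daughter-cell separation genes fell. For flocculins the median was 0.39, the mean -0.39 and the test pointed down. For ergosterol the median was -0.10, the mean 0.04 and the test pointed up. Regroupings that mixed WT and mutant libraries made camera with its preset correlation call up to 20 lists. They kept part of the difference between the strains, so this number is not a rate of false calls. Most list calls were lost with an estimated correlation, so a list call alone is weak evidence here.

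The comparison of rpb1-TPY,FSP with WT asks the same of the polymerase side. Ribosomal protein genes fell in 135 of 138 cases, while 17 of 21 glucose-repressed carbon genes and 19 of 29 general stress genes rose. The list call held for ribosomal proteins (adjusted p = 0.0265 with an estimated correlation) and was lost for the others (adjusted p = 0.0614 and 0.302 with an estimated correlation). In all 1978 genes changed, 1058 up and 920 down, which is 35.2% of those tested, and 388 rose and 167 fell by 2-fold or more. IMD2 rose to 486 ± 78.5 CPM (log2 3.65 ± 0.18, adjusted p = 2.71e-11) and HPF1 to 218 ± 29.3 CPM (3.95 ± 0.27, adjusted p = 2.96e-09), while FLO11 fell to 21.1 ± 0.84 CPM (-3.99 ± 0.32, adjusted p = 2.21e-08). By mid-gene counts FLO11 had -2.48, so the size of its fall is uncertain. TRP1 stayed at the WT level, at 0.77 ± 0.44 CPM.

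YHR214W, a gene with near-identical copies, had 6, 35 and 71 counts in rpb1-TPY,FSP libraries 1, 2 and 3 and 0 in WT, at least 28.4-fold higher against a floor of 3 counts over the group. This bound was 45.7 without rpb1-TPY,FSP library 1, 15 without library 3 and 17.5 and 18 without WT libraries 1 and 2. UTR5 had 98 counts against 2 (ratio 37.3, 95% exact counting interval 10 to 312). Other large rises were in YIL169C (4.90 ± 0.46), YAR068W (4.44 ± 0.74), YER085C (4.00 ± 0.61), FYV12 (3.93 ± 0.57), HRA1 (3.89 ± 1.00) and the galactose gene GAL10 (3.74 ± 0.50). HRA1 had 73, 8 and 11 counts in libraries 1, 2 and 3, and was not called without library 1 (2.51, adjusted p = 0.068). After FLO11 the largest falls were in PWR1 (-3.02 ± 0.48), RPL36A (-2.03 ± 0.14), RPL26A (-1.90 ± 0.15), FAA3 (-1.86 ± 0.16), RPL27B (-1.80 ± 0.12), RPS23A (-1.77 ± 0.13), YLR126C (-1.77 ± 0.34), the small nucleolar RNA snR33 (-1.73 ± 0.21) and RPL18B (-1.72 ± 0.15).

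Ribosomal protein genes fell in 135 of 138 cases in rpb1-TPY,FSP (135 adjusted over the list alone; median -1.09, camera adjusted p = 6.46e-107), a call that held at adjusted p = 0.0265 with an estimated correlation. It was lost in that test without the libraries numbered 1 of both double mutants (adjusted p = 0.0634 with an estimated correlation). Ribosome biogenesis genes fell in 22 of 43 cases (25 adjusted over the list alone; median -0.45, camera adjusted p = 2.89e-07, adjusted p = 0.498 with an estimated correlation), with NOP1 at -1.09 and NOP58 at -1.02. This was 34 of 43 without the libraries numbered 1 of both double mutants (median -0.624, camera adjusted p = 1.72e-09, adjusted p = 0.383 with an estimated correlation). Glycolysis and fermentation fell in 10 of 16 genes and rose in 1 (10 and 1 adjusted over the list alone; median -0.57, camera adjusted p = 0.00131, adjusted p = 0.506 with an estimated correlation). Histone genes fell in 6 of 10 cases (7 adjusted over the list alone; median -0.41, camera adjusted p = 0.00447, adjusted p = 0.506 with an estimated correlation), with HTA1 at -0.95 ± 0.15. RNA polymerase II subunit genes fell in 6 of 11 cases (6 adjusted over the list alone; median -0.36, camera adjusted p = 0.0211, adjusted p = 0.246 with an estimated correlation).

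Glucose-repressed genes rose in 17 of 21 cases in rpb1-TPY,FSP (17 adjusted over the list alone; median 1.601, camera adjusted p = 8.4e-08, adjusted p = 0.0614 with an estimated correlation), with ALD4 at 2.52 and PCK1 at 2.21. With an estimated correlation the list gained a call when the libraries numbered 1 of both double mutants were left out (camera adjusted p = 0.0272). ADH2 had 3.40 by full-gene and -0.11 by mid-gene sense counts. General stress genes rose in 19 of 29 (19 adjusted over the list alone; median 0.72, camera adjusted p = 6.51e-07, adjusted p = 0.302 with an estimated correlation), with SPI1 at 2.66. The start-site and upstream-transcription genes IMD2, SER3 (2.86 ± 0.29) and URA8 (1.07 ± 0.15) rose, 3 of 5 (3 adjusted over the list alone; median 1.07, camera adjusted p = 2.62e-06, adjusted p = 0.0516 with an estimated correlation). The iron regulon rose in 14 of 22 genes (15 adjusted over the list alone; median 0.57, camera adjusted p = 0.000156, adjusted p = 0.475 with an estimated correlation), with SIT1 at 2.92 ± 0.31. Thiamine synthesis rose in 10 of 17 (11 adjusted over the list alone; median 0.71, camera adjusted p = 0.00141, adjusted p = 0.169 with an estimated correlation), where THI5 had 48 counts against 2 in WT (ratio 18.2, 95% exact counting interval 4.78 to 155). The phosphate regulon rose in 6 of 15 (6 adjusted over the list alone; median 0.45, camera adjusted p = 0.0369, adjusted p = 0.151 with an estimated correlation), with PHO12 at 3.51 and PHO5 at 1.93.

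In rpb1-TPY,FSP the PAU and COS families rose in 9 of 16 genes (10 adjusted over the list alone; median 0.89, camera adjusted p = 0.00133, adjusted p = 0.237 with an estimated correlation). All 3 alpha-specific genes rose (3 adjusted over the list alone; median 1.83, camera adjusted p = 0.0291, adjusted p = 0.151 with an estimated correlation), as did 6 of 13 DNA damage genes (6 adjusted over the list alone; median 0.31, camera adjusted p = 0.0332, adjusted p = 0.432 with an estimated correlation). Meiosis genes rose in 7 of 25 cases (5 adjusted over the list alone; median 0.60, camera adjusted p = 0.0369, adjusted p = 0.432 with an estimated correlation), and oxidative phosphorylation in 8 of 33 (6 adjusted over the list alone; median 0.31, camera adjusted p = 0.0467, adjusted p = 0.935 with an estimated correlation). Cell wall genes (11 up, 2 down of 23; 11 and 3 adjusted over the list alone; camera adjusted p = 0.0535), a-specific genes (4 up of 7; 4 adjusted over the list alone; 0.127), markers (2 up of 7; 1 adjusted over the list alone; 0.744) and amino acid synthesis (5 up, 1 down of 35; 3 and 0 adjusted over the list alone; 0.37) were not called. MF(ALPHA)2 (2.045) was not called without rpb1-TPY,FSP library 1 (adjusted p = 0.125) or WT library 1 (0.0543). Without the libraries numbered 1 of both double mutants 2 of 3 alpha-specific genes rose and that list (median 1.207, camera adjusted p = 0.0626) and the meiosis list (0.0626) were not called. Cell wall genes were called in that setting (12 up, 0 down; camera adjusted p = 0.000546), but not in the stricter test (adjusted p = 0.394 with an estimated correlation). There 19 of 33 oxidative phosphorylation genes rose (median 0.474, adjusted p = 0.716 with an estimated correlation), amino acid synthesis had 4 up and 6 down, and the median of DNA damage genes was 0.589. PCA1 and STE11 rose again among the 5 genes with cryptic internal promoters (2 adjusted over the list alone; camera adjusted p = 0.35, fry adjusted p = 0.0108).

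**Figure D2:**
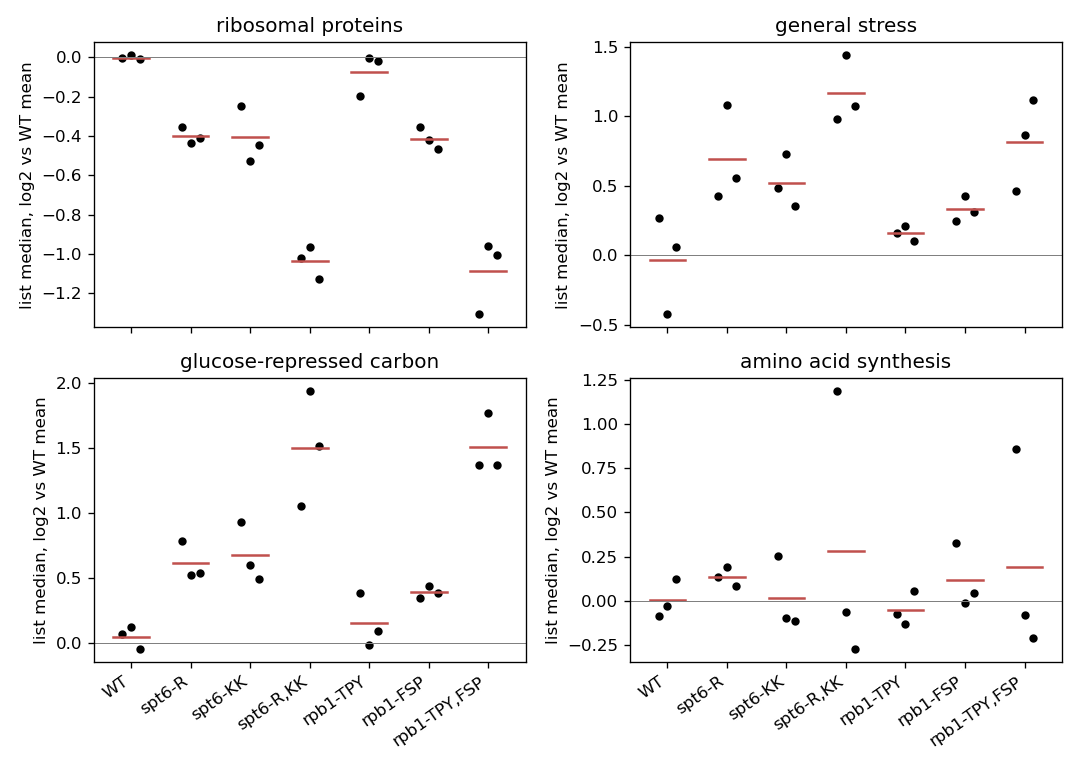
Median log2 value of the genes of 4 lists against the mean of WT, with 1 point per library and a bar for the mean of 3 libraries. For ribosomal protein genes the means of these medians were -1.04 ± 0.08 (SD, n = 3) in spt6-R,KK and -1.09 ± 0.19 in rpb1-TPY,FSP, and -0.07 ± 0.11 in rpb1-TPY.

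The comparison of each single change with WT shows which part of the double it carries. In spt6-R 477 genes changed, 226 up and 251 down. IMD2 rose by 3.19 ± 0.17 (adjusted p = 1.31e-10), SER3 by 2.44 ± 0.29 and URA8 by 1.18 ± 0.15, so that 3 of the 5 start-site and upstream-transcription genes rose (3 adjusted over the list alone; median 1.18, camera adjusted p = 5.28e-17, adjusted p = 0.00112 with an estimated correlation). TRP1 rose by 4.80 ± 0.25 and the alpha-factor gene MF(ALPHA)2 by 2.56 ± 0.57 (adjusted p = 0.0107). FLO11 (-1.11 ± 0.28; -0.88 by mid-gene counts), the nuclear envelope gene BRR6 (-1.03 ± 0.28) and ADF1 (-0.98 ± 0.26) fell most. Ribosomal protein genes fell in 70 of 138 cases (107 adjusted over the list alone; median -0.40, camera adjusted p = 6.99e-39, adjusted p = 0.141 with an estimated correlation) and ribosome biogenesis genes in 25 of 43 (38 adjusted over the list alone; median -0.53, camera adjusted p = 8.44e-19, adjusted p = 0.176 with an estimated correlation). General stress genes rose in 8 of 29 cases (20 adjusted over the list alone; median 0.71, camera adjusted p = 4.61e-11, adjusted p = 0.141 with an estimated correlation). PHO5 (0.03, adjusted p = 0.972) and SIT1 (0.30, adjusted p = 0.582) did not pass. The count of genes fell to 110 without WT library 2, 160 without WT library 3, 131 without spt6-R library 2 and 149 without spt6-R library 3, and was 902 with these 2 strains fitted alone. FLO11 lost its call without WT library 2 or 3 or spt6-R library 1 or 3 (adjusted p 0.0526 to 0.151), BRR6 without WT library 2 or any spt6-R library (0.0518 to 0.177), ADF1 without WT library 2 or 3 or spt6-R library 2 or 3 (0.0695 to 0.138), and MF(ALPHA)2 without WT library 3 (0.0524).

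In spt6-KK 747 genes changed, 357 up and 390 down. IMD2 rose by 3.27 ± 0.18 (adjusted p = 8.79e-11), SER3 by 2.48 ± 0.29 and URA8 by 0.99 ± 0.15, again 3 of 5 genes of their list (3 adjusted over the list alone; median 0.99, camera adjusted p = 6.39e-11, adjusted p = 0.00871 with an estimated correlation). TRP1 (4.83 ± 0.24) and YLR030W (2.57 ± 0.57) rose as well, and FLO11 (-3.05 ± 0.30, adjusted p = 2.06e-06), PWR1 (-2.56 ± 0.46) and the methionine synthesis gene MET2 (-1.47 ± 0.36) fell most. By mid-gene counts FLO11 had -2.25. Ribosomal protein genes fell in 73 of 138 cases (98 adjusted over the list alone; median -0.40, camera adjusted p = 1.83e-35, adjusted p = 0.483 with an estimated correlation), and general stress genes rose in 8 of 29 (8 adjusted over the list alone; median 0.50, camera adjusted p = 0.000143, adjusted p = 0.628 with an estimated correlation). The gene count was 308 without WT library 2, 389 without WT library 3, 268 without spt6-KK library 2 and 363 without spt6-KK library 3. MET2 lost its call without WT library 2 (-0.835, adjusted p = 0.138) or spt6-KK library 2 (0.0595), and YLR030W without WT library 2 (0.0507).

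In rpb1-FSP 132 genes changed, 50 up and 82 down. IMD2 rose by 2.90 ± 0.17 (adjusted p = 6.68e-10), SER3 by 2.19 ± 0.28 and URA8 by 0.94 ± 0.15, once more 3 of 5 genes (3 adjusted over the list alone; median 0.94, camera adjusted p = 2.1e-18, adjusted p = 0.000611 with an estimated correlation). TRP1 (4.70 ± 0.25) and YIL169C (2.56 ± 0.46) were the other large rises, and FLO11 (-2.08 ± 0.29; -1.59 by mid-gene counts), the pectinase gene PGU1 (-1.83 ± 0.47) and PWR1 (-1.81 ± 0.44) the largest falls. Ribosomal protein genes fell in 46 of 138 cases (110 adjusted over the list alone; median -0.41, camera adjusted p = 1.88e-55, adjusted p = 0.136 with an estimated correlation). The gene count was 52 without WT library 2, 70 without WT library 3, 73, 71 and 49 without rpb1-FSP libraries 1, 2 and 3, 247 by DESeq2 and 437 with these 2 strains fitted alone. PGU1 and PWR1 lost their calls without WT library 2 or any rpb1-FSP library (adjusted p 0.0824 to 0.247), and PGU1 also without WT library 3 (0.0772).

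In rpb1-TPY 3 genes changed, all upward, with 88 at an unadjusted p under 0.05 where chance would give 281. DESeq2 also called 3. They were TRP1 (4.56 ± 0.25, adjusted p = 2.48e-10) and a pair of neighbours on chromosome XIII, the carnitine acetyltransferase gene CAT2 (192788 to 194800; 1.24 ± 0.21, adjusted p = 0.0142) and the chromatin remodelling gene VPS71 (194913 to 195755; 1.05 ± 0.18, adjusted p = 0.0142). IMD2 (0.30, adjusted p = 1) and SER3 (0.24, adjusted p = 1) did not pass. None of the ribosomal protein genes passed (0 adjusted over the list alone), although camera called the list at a median of -0.07 (adjusted p = 3.01e-06, adjusted p = 0.894 with an estimated correlation). The marker list held at adjusted p = 0.0228 with an estimated correlation, with TRP1 as its 1 called gene of 7 (1 adjusted over the list alone), and fry called 0 of 33 lists where camera called 9 and 1 with an estimated correlation. Both CAT2 and VPS71 lost their calls, so that the count was 1, without WT library 1, WT library 2 or rpb1-TPY library 2 (adjusted p 0.0973 to 0.254) and with these 2 strains fitted alone. CAT2 also did without rpb1-TPY library 1 (0.153) and VPS71 without library 3 (0.0617). Mid-gene counts called 6 genes, 2 of them among the 3, and camera called 4 lists without rpb1-TPY library 2.

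Camera called 19 lists in spt6-R, 12 in spt6-KK, 19 in spt6-R,KK, 9 in rpb1-TPY, 13 in rpb1-FSP and 16 in rpb1-TPY,FSP. With an estimated correlation the calls that held were the start-site and upstream-transcription genes in spt6-R, spt6-KK, rpb1-FSP and spt6-R,KK, ribosomal proteins in both double mutants, and the markers in rpb1-TPY. fry called 15, 8, 20, 0, 4 and 17 lists in the same order of strains.

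**Figure D3:**
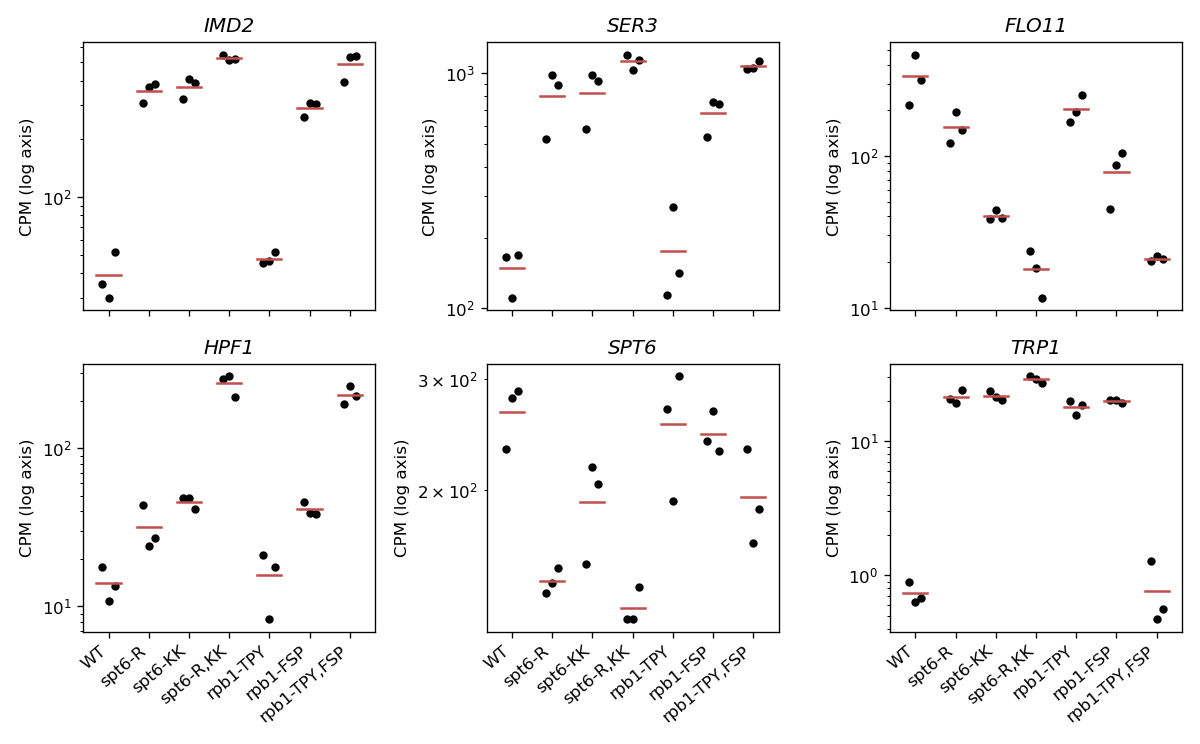
CPM of IMD2, SER3, FLO11, HPF1, SPT6 and TRP1 in every library on a log axis, 1 point per library with the mean of 3. IMD2 had means of 39.0 CPM in WT, 47.8 in rpb1-TPY and 290 to 525 in the other mutants, and TRP1 stayed below 1.5 CPM in WT and rpb1-TPY,FSP.

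How alike the mutants were was measured across genes, which are not independent replicates. All mutants share the 3 WT libraries, and simulated series with unchanged groups gave correlations of 0.504 to 0.529 from that alone. Log2 fold changes of spt6-R,KK and rpb1-TPY,FSP had r = 0.951 (Spearman 0.926) against 0.521 simulated. Their covariance of 0.453 exceeded the simulated 0.0328 by 0.42. Of their genes 874 rose in both (204 by chance for independent lists) and 781 fell in both (161 by chance), and none changed in opposite directions. The simulated series had an overlap of 0, but with no effects in them they give no baseline for overlap among real calls. The 3 WT libraries cannot be divided into groups of at least 2, so part of the excess in r and in overlap may come from shared controls. The difference of covariances leaves out what a simulated WT group adds on average. Simulated libraries were drawn independently, so a deviation shared by libraries of the same number would remain in that difference. spt6-R and rpb1-FSP had r = 0.77 (0.504 simulated), spt6-R and spt6-KK 0.675 (0.515 simulated), and rpb1-FSP and its double mutant 0.715 (0.519 simulated), with a slope of 1.39. The pairs with rpb1-TPY had r of 0.264 to 0.45, all below the simulated values. The simulated groups had no effects, and effects in 1 mutant of a pair can lower r. Covariances with rpb1-TPY exceeded the simulated ones for spt6-R (0.0368 against 0.0322), spt6-KK (0.0438 against 0.0327), spt6-R,KK (0.0459 against 0.0326) and rpb1-TPY,FSP (0.0404 against 0.0328). For rpb1-FSP the covariance was 0.03 against 0.0319. No spread of the simulated covariances was computed, so these small differences cannot be told from noise. TRP1, whose genotype is not given, rose in rpb1-TPY, rpb1-FSP and every SPT6 mutant and adds to the covariances among them. They are therefore no evidence of effects shared with rpb1-TPY.

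Compared directly, spt6-R,KK and rpb1-TPY,FSP differed in 2 genes by edgeR and 2 by DESeq2, with 198 at an unadjusted p under 0.05 where chance would give 281. TRP1 was higher in spt6-R,KK by 5.11 ± 0.22 (adjusted p = 3.63e-12), where the marker genotype of these strains is not given. BPL1 (chromosome IV 203039 to 205111), the biotin ligase gene that ends next to RPO21, was higher by 0.73 ± 0.13 (adjusted p = 0.031). Against WT BPL1 fell by 0.76 ± 0.13 in rpb1-FSP (adjusted p = 0.00199) and by 0.53 ± 0.13 in rpb1-TPY,FSP (adjusted p = 0.00277), and had -0.53 ± 0.13 (adjusted p = 0.661) in rpb1-TPY and 0.20 ± 0.13 (adjusted p = 0.225) in spt6-R,KK. BPL1 was no longer called when any 1 of the 6 libraries was left out (0.64 to 0.81) or by mid-gene counts (0.73), which left TRP1 alone. Camera called 9 lists between them, 8 toward spt6-R,KK and 1 toward rpb1-TPY,FSP. Only the marker list held (camera adjusted p = 8.82e-18, adjusted p = 0.00124 with an estimated correlation), with TRP1 as its 1 called gene of 7 (1 adjusted over the list alone). The other 8 were lost (adjusted p 0.441 to 0.78 with an estimated correlation), among them the general stress list with 0 of 29 genes called alone (0 adjusted over the list alone) and a median of 0.35 toward spt6-R,KK (camera adjusted p = 2.52e-09). A p that misses the threshold does not show that both strains act alike.

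**Figure D4:**
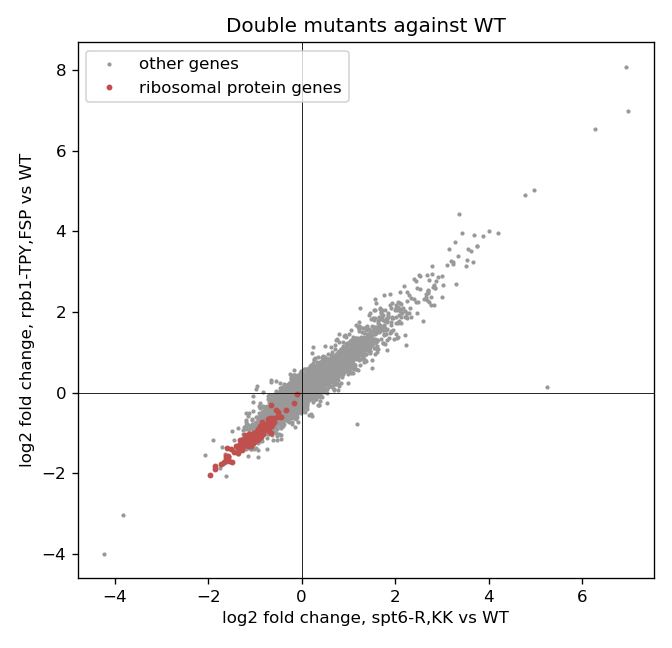
Log2 fold change against WT of each tested gene in spt6-R,KK (x) and rpb1-TPY,FSP (y), 1 point per gene, across 5618 genes (r = 0.951). TRP1 lies far from the diagonal, and the ribosomal protein genes lie at the lower left.

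Whether the double mutants are the sum of their singles was tested as an interaction on the log2 scale. For rpb1-TPY,FSP 179 genes were non-additive, 74 above and 105 below the sum (939 at an unadjusted p under 0.05). The balance turned without rpb1-TPY,FSP library 1 (254 genes, 135 above and 119 below) and without the libraries numbered 1 of both double mutants (366 genes, 190 above and 176 below). Above it were YML007C-A (3.28 ± 0.87), YNR062C (2.95), the aromatic aminotransferase gene ARO9 (2.65 ± 0.52, adjusted p = 0.00856), PHO5 (2.65 ± 0.54, adjusted p = 0.00958) and FMP45 (2.63 ± 0.59). Below it were TRP1 (-9.13 ± 0.34), the kynurenine pathway gene BNA7 (-1.30 ± 0.26), PTC7 (-1.30), RPS9A (-1.28 ± 0.23) and RPL36A (-1.21 ± 0.19, adjusted p = 0.00292). TRP1 was low in WT and rpb1-TPY,FSP and high in both singles. Any effect of a marker difference on other genes would thus enter this contrast, and that of spt6-R,KK as well. In rpb1-TPY, where TRP1 also exceeded WT, 3 genes passed against WT. Ribosomal protein genes lay below the sum in 64 of 138 cases (111 adjusted over the list alone; median -0.61, camera adjusted p = 7.75e-64, adjusted p = 0.101 with an estimated correlation), and glucose-repressed genes above it in 3 of 21 (6 adjusted over the list alone; median 1.10, camera adjusted p = 8.74e-06, adjusted p = 0.131 with an estimated correlation). The count was 107, 108, 113, 115 and 96 without WT library 1, WT library 2, rpb1-TPY library 2, rpb1-TPY library 3 and rpb1-FSP library 2. YML007C-A and YNR062C lost their calls without WT library 2, rpb1-TPY library 2, rpb1-FSP library 2 or 3, rpb1-TPY,FSP library 3 and further libraries (adjusted p 0.0551 to 0.169), and FMP45 (0.0525) and PTC7 (0.0543) without rpb1-TPY library 2.

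For spt6-R,KK 20 genes were non-additive, 6 above and 14 below the sum (840 at an unadjusted p under 0.05; 102 by DESeq2). With replicate number as a block there were 80 (29 above, 51 below), without the libraries numbered 1 of both double mutants 124 (54 above, 70 below), and with only the compared strains 44. All 20 were among the 80 and among the 124. Without spt6-R,KK library 3 as many lay above as below the sum (17 each). Above it were the arginine catabolism gene CAR2 (1.52 ± 0.21, adjusted p = 0.000882), SPC25 (1.35), DEP1 (1.01), ESBP6 (0.93) and PUS2 (0.88). Below it were TRP1 (-4.38 ± 0.30), IMD2 (-2.70 ± 0.23, adjusted p = 4.65e-07), SER3 (-1.99 ± 0.39, adjusted p = 0.0218), the biotin synthesis gene BIO2 (-1.73 ± 0.25) and the sulfate assimilation gene MET3 (-1.69 ± 0.16, adjusted p = 1.12e-06). Against WT IMD2 had risen by 3.19 in spt6-R, 3.27 in spt6-KK and 3.76 in the double mutant. The start-site and upstream-transcription genes lay below the sum in 2 of 5 cases (3 adjusted over the list alone; median -0.85, camera adjusted p = 3.04e-09, adjusted p = 0.0168 with an estimated correlation), and the marker list had a median of 0.46 but a mean of -0.61 and a test that pointed down (camera adjusted p = 0.0402, adjusted p = 0.775 with an estimated correlation). The count was 6 and 10 without WT libraries 2 and 3, 8 and 13 without spt6-R libraries 2 and 3, 8 and 11 without spt6-KK libraries 2 and 3, and 60, 12 and 34 without spt6-R,KK libraries 1, 2 and 3. SER3 lost its call without WT library 2, spt6-R library 2 or 3, spt6-KK library 2 or 3 or spt6-R,KK library 2 (adjusted p 0.0526 to 0.0865), and SPC25, DEP1, ESBP6 and PUS2 each without WT library 2 or 3, spt6-R library 2, spt6-KK library 2 and further libraries.

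Because Spt6 acts during elongation, the sense counts over the middle 70% of each gene were set against the full-gene counts, as a difference of log2 CPM in 5343 genes. Full-gene counts hold all signal within a gene, so the difference may mix strand with position. It was compared with WT in each mutant. The difference changed in 55 genes in spt6-R,KK (32 up, 23 down) and 79 in rpb1-TPY,FSP (45 up, 34 down), against 3 in spt6-R, 6 in spt6-KK, 3 in rpb1-TPY and 4 in rpb1-FSP. Without the median centring, which was added after seeing simulated data, there were 94 genes in spt6-R,KK (73 up, 21 down) and 151 in rpb1-TPY,FSP (112 up, 39 down), so the balance of directions depends on it. FLO11 had relatively more mid-gene counts by 1.81 ± 0.19 in spt6-R,KK (limma adjusted p = 0.000143) and by 1.48 ± 0.19 in rpb1-TPY,FSP (adjusted p = 0.000614). In spt6-R,KK its mid-gene values of 37.0, 48.5 and 39.2 CPM lay above its full-gene values of 23.7, 18.3 and 11.6 CPM, which a part of the gene could not reach if both tables counted reads alike, so this difference is uncertain. The small nucleolar RNA gene snR78 had 0.62 ± 0.08 and 0.58 ± 0.08 in these strains, and also changed in spt6-R (0.52), spt6-KK (0.48) and rpb1-FSP (0.61). It had 1.07 times as many mid-gene as full-gene counts over the series, so its difference is uncertain too. In spt6-R,KK and rpb1-TPY,FSP ADH2 had -3.48 ± 0.32 (limma adjusted p = 3.2e-05) and -3.52 ± 0.32 (adjusted p = 2.69e-05), and YFR032C-B -1.41 ± 0.22 and -1.37 ± 0.22. ADH2 also changed in spt6-R (-2.36), spt6-KK (-2.63) and rpb1-FSP (-1.95), and YFR032C-B in rpb1-FSP (-1.28). Both have several times more mid-gene than full-gene counts over the series (4.10 and 19.3 times), so the tables do not count reads alike for them, for a reason that was not tested. IDP2, an isocitrate dehydrogenase gene, rose in the mid-gene share by 0.48 ± 0.07 in spt6-KK and 0.57 ± 0.07 in rpb1-TPY, PFK26 by 0.23 ± 0.04 in rpb1-TPY, and YDR341C fell by 0.05 ± 0.01 in spt6-R. By mid-gene counts FLO11 itself had -2.43 in spt6-R,KK and -2.48 in rpb1-TPY,FSP, against -4.23 and -3.99 by full-gene counts.

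The counts of genes with a changed mid-gene share moved with the samples used. In spt6-R,KK it was 0 with only the compared strains fitted (826 genes at an unadjusted p under 0.05 in the fit of all strains), 35, 28 and 35 without WT libraries 1, 2 and 3, and 33 without spt6-R,KK library 2 or 3. In rpb1-TPY,FSP it was 16 with only the compared strains (668 at an unadjusted p under 0.05 in the fit of all strains), 51 and 44 without WT libraries 1 and 3, and 52 without rpb1-TPY,FSP library 2. In spt6-KK it was 2, 3 and 1 without WT libraries 1, 2 and 3, and 3, 2 and 2 without spt6-KK libraries 1, 2 and 3. In rpb1-TPY it was 1 without any 1 WT library and 0 with only the compared strains (409 at an unadjusted p under 0.05 in the fit of all strains). In rpb1-FSP it was 2 and 1 without WT libraries 2 and 3 and 2 without rpb1-FSP library 2 or 3, and in spt6-R it was 0 without spt6-R library 2 (405 at an unadjusted p under 0.05 with all libraries).

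The authors' deposited DESeq2 table called 586 genes in spt6-R, 841 in spt6-KK, 2055 in spt6-R,KK, 3 in rpb1-TPY, 231 in rpb1-FSP and 1973 in rpb1-TPY,FSP by full-gene counts, and 520, 773, 2008, 6, 239 and 1911 by mid-gene counts. Across genes its log2 fold changes ranked as the edgeR values did, with Spearman correlations of 0.994 to 0.997 for full-gene counts. Both rest on the same libraries and counts, so this is no independent check of the results. Genes are not independent replicates. Scaling by median of ratios in place of TMM moved the median of all genes by less than 0.1 in each comparison.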

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

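The tests of depth, sample labels, a shared batch, composition, paralog reads, introns and read-through, the counts of regroupings and the exchange of library numbers were chosen after the result was seen; the test of gene length was written before.

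Ribosomal protein genes had lower counts in both double mutants, with medians of -1.03 in spt6-R,KK and -1.09 in rpb1-TPY,FSP. The tables argue against composition, since the 138 most abundant other genes had a median of at lowest -0.21, and against paralog reads, since the 20 genes with no A or B copy had at highest -0.839. They also argue against gene length, where genes matched on length and expression had at lowest -0.116, and against introns, since the 49 genes with 1 coding segment had at highest -0.978 and 176 other genes with introns had -0.06 and 0.00. A lower demand for ribosomes in strains that may grow more slowly stays open as a hypothesis; growth was not measured here and no biological explanation was tested.

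SRG1 (chromosome V 322212 to 322762), the noncoding RNA transcribed across the SER3 promoter, is counted only in the mid-gene table and stood out as a signal outside the main measurement. It was higher than in WT by 0.97 in spt6-R, 0.90 in spt6-KK, 1.604 ± 0.12 in spt6-R,KK (edgeR adjusted p = 7.06e-09), 1.05 in rpb1-FSP and 1.68 in rpb1-TPY,FSP (adjusted p = 3.66e-09), with 0.16 in rpb1-TPY (adjusted p = 0.999). SER3 (322686 to 324095), which SRG1 transcription represses, rose in the same strains. Reads running from SRG1 into SER3 are a candidate explanation, but the rise of SER3 per base was at least 4.64 times that of SRG1 in these mutants (in rpb1-TPY,FSP; 8.81 times in spt6-KK), which argues against read-through as the whole of it. Whether less repression per SRG1 transcript occurs in the mutants was not tested, and the annotated genes overlap.

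Amino acid synthesis genes were high in the libraries numbered 1 of both double mutants, with medians of 1.19 in spt6-R,KK 1 and 0.86 in rpb1-TPY,FSP 1 against -0.27 to 0.33 in the other libraries. Depth is argued against by other libraries at least as deep, whose highest median was 0.256. A wrong label is argued against by the ribosomal protein medians of both libraries, at highest -1.02, and TRP1 was at 30.6 CPM in spt6-R,KK 1 and 1.27 CPM in rpb1-TPY,FSP 1, each near its strain. A batch shared by libraries of the same number stays open. Library 1 had the highest list median in 4 of 7 strains (2.33 by chance, one-sided exact binomial p = 0.173), which decides nothing for these genes. Both double mutants, which raised the question, are among the 4, so this chance value and p are not those of a fresh test. Over all genes 18 of 21 libraries correlated best with their own number, with a mean r of 0.124, which 42 of 46656 exchanges of the numbers within strains reached (exact p = 0.0009). With replicate number as a block the list had medians of 0.37 in spt6-R,KK (camera adjusted p = 0.0441) and 0.222 in rpb1-TPY,FSP (0.287). No biological explanation was tested.

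Genes whose change in the double mutant differed from the sum of its singles numbered 20 for spt6-R,KK and 179 for rpb1-TPY,FSP. By DESeq2 they numbered 102 and 260, and these counts were not tested against each other. In both cases 6 of 100 groupings of the 12 libraries gave as many genes, the real grouping among them. The highest other counts were 662 and 1905. Regrouping carries the differences between strains into the interaction, so these counts show a structure of the samples and do not say whether chance gives the real ones. For rpb1-TPY,FSP the regrouping with 1905 kept all rpb1-FSP libraries in 1 group and all double-mutant libraries in another and mixed WT with rpb1-TPY.

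For comparisons of 3 against 3 libraries the 10 splits, which include the real grouping, are too few for a share under 0.05. Every other split mixes the strains unevenly and keeps part of the difference between them, so its count is no chance value. For genes changed against WT 1 of 10 splits reached the real count in every mutant: spt6-R 477 (highest other 0), spt6-KK 747 (0), spt6-R,KK 2064 (0), rpb1-TPY 3 (1), rpb1-FSP 132 (0) and rpb1-TPY,FSP 1978 (0). For lists the numbers were 1 of 10 in spt6-R (19, highest other 15), 1 in spt6-KK (12, 11), 3 in spt6-R,KK (19, 20), 6 in rpb1-TPY (9, 15), 1 in rpb1-FSP (13, 9) and 2 in rpb1-TPY,FSP (16, 17). For the mid-gene share they were 1 of 10 in each, with 3 (highest other 1), 6 (1), 55 (1), 3 (1), 4 (0) and 79 (0) in the same order of strains. Between the double mutants 5 of 10 splits reached 2 genes, and the highest other, 115, put spt6-R,KK 1 and 2 with rpb1-TPY,FSP 1, which points to a structure of the samples.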

How the results depend on the processing

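Robust estimation, both double-mutant libraries numbered 1 left out together, and no median centring were chosen after seeing the data. The other alternatives were set before. Of 323 results for named genes, 220 kept their direction and their side of the threshold under every alternative and 28 changed sign under at least 1. Over all alternatives 4473 values stayed the same, 253 lost and 34 gained a call, and 60 changed sign. The cause was not tested unless given. The counts of genes changed in spt6-R,KK and rpb1-TPY,FSP stayed within 1.5 times of 2064 and 1978 under every alternative tried. In simulated data shaped like these counts 42.5% of 1.5-fold and 94.7% of 2-fold changes were recovered. Depth was not varied there, so what it limits was not tested. In a fit that leaves out 1 library the strain keeps 2, whose spread is pooled with that of the other strains.

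Counts that moved were as follows. With an estimated correlation camera called 1 list in spt6-R, 1 in spt6-KK, 2 in spt6-R,KK, 1 in rpb1-TPY, 1 in rpb1-FSP and 1 in rpb1-TPY,FSP. The test fry called 0 in rpb1-TPY and 4 in rpb1-FSP. Mid-gene counts called 6 genes in rpb1-TPY, 2 of them shared with the 3, and 1 gene between the double mutants. With replicate number as a block the spt6 interaction had 80 genes and the mid-gene share 2 in spt6-KK and 1 in rpb1-TPY. In that setting spt6-R had 607, spt6-KK 918, spt6-R,KK 2218, rpb1-TPY 3, rpb1-FSP 177 and rpb1-TPY,FSP 2141 genes. No label says that a number marks a batch, and same-numbered libraries had a residual correlation of -0.416 to 0.485 over 63 pairs, 39 of them above 0.1 (mean 0.124, against -0.0602 for other numbers). As a hint from the data, 18 of 21 libraries correlated best with their own number, and 42 of 46656 exchanges of the numbers gave a mean as large (exact p = 0.0009, a test chosen after seeing the data). With only the compared strains fitted there were 902 genes in spt6-R, 1 in rpb1-TPY, 437 in rpb1-FSP, 44 in the spt6 interaction and 1 between the double mutants. The mid-gene share in that setting had 1 in spt6-KK, 0 in spt6-R,KK, 0 in rpb1-TPY, 2 in rpb1-FSP and 16 in rpb1-TPY,FSP, with fewer samples to estimate the spread. DESeq2 called 247 genes in rpb1-FSP and 102 in the spt6 interaction. With both double-mutant libraries numbered 1 left out, spt6-R,KK had 2130 genes (1816 shared with the 2064) and rpb1-TPY,FSP 2107 (1763 shared with the 1978). The spt6 interaction then had 124 genes and the rpb1 interaction 366, and 1 gene differed between the double mutants. In that setting ribosomal proteins fell in 136 and 132 of 138 genes, with adjusted p = 0.0449 and 0.0634 with an estimated correlation. A minimum of 100 counts gave 0 genes for the mid-gene share in rpb1-TPY by limma, and no median centring gave 94 in spt6-R,KK and 151 in rpb1-TPY,FSP.

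Leaving out 1 library at a time gave these ranges. Genes changed were 110 to 489 in spt6-R, 268 to 959 in spt6-KK, 1546 to 1987 in spt6-R,KK, 1 to 3 in rpb1-TPY, 49 to 110 in rpb1-FSP, 1476 to 1948 in rpb1-TPY,FSP, 1 to 1 between the double mutants, 6 to 60 in the spt6 interaction and 96 to 254 in the rpb1 interaction. Lists called were 18 to 20 in spt6-R, 10 to 13 in spt6-KK, 17 to 21 in spt6-R,KK, 4 to 10 in rpb1-TPY, 9 to 15 in rpb1-FSP and 15 to 16 in rpb1-TPY,FSP. Genes with a changed mid-gene share were 0 to 4 in spt6-R, 1 to 3 in spt6-KK, 28 to 76 in spt6-R,KK, 1 to 2 in rpb1-TPY, 1 to 5 in rpb1-FSP and 44 to 67 in rpb1-TPY,FSP. The correlation across genes was 0.907 to 0.954 between the double mutants, 0.653 to 0.77 between spt6-R,KK and rpb1-FSP, and 0.621 to 0.732 between rpb1-FSP and rpb1-TPY,FSP.

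Among named genes whose log2 fold change turned, ADH2 was called by full-gene counts (3.344 in spt6-R,KK and 3.398 in rpb1-TPY,FSP) and not by mid-gene counts (-0.157 and -0.113). The others were not called with all libraries. Their values in spt6-R,KK were VTC4 -0.006 with size factors by median of ratios, -0.001 with no filter and -0.007 by DESeq2. In rpb1-FSP RPO21 had 0.004 with no filter and 0.002 with at least 50 counts in 3 libraries. By mid-gene counts PHO81 had 0.026 in rpb1-TPY,FSP. With replicate number as a block BAR1 had -0.023 in spt6-R,KK and HIS3 -0.01 in rpb1-TPY,FSP. With both libraries numbered 1 left out, spt6-R,KK had VTC2 0.017, VTC4 -0.012, TNA1 -0.264, BAR1 -0.233 and HIS3 -0.399. BNA1 had -1.068 there and passed the test (adjusted p = 0.0258). In rpb1-TPY,FSP that setting gave VTC4 0.046, ASG7 -0.676, TRP1 -0.5 and HIS3 -0.456, and RPO21 had -0.047 between the double mutants.

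Leaving out 1 library at a time, the turned values had these ranges. In spt6-R,KK they were RPO21 -0.096 to 0.004, HTB2 -0.083 to 0.122, PHM6 -0.746 to 0.064 and VTC1 -0.065 to 0.034. VTC2 had -0.105 to 0.019, PHO81 -0.078 to 0.181, VTC4 -0.027 to 0.043 and ADE12 -0.655 to 0.123. TNA1 had -0.26 to 0.279, BNA1 -1.063 to 0.824, BAR1 -0.23 to 0.179 and HIS3 -0.396 to 0.425. In rpb1-TPY SPT6 had -0.208 to 0.103 and RPO21 -0.298 to 0.003, and RPO21 had -0.06 to 0.052 in rpb1-FSP and -0.079 to 0.222 in the rpb1 interaction. In rpb1-TPY,FSP HTB2 had -0.108 to 0.195, PHO81 -0.163 to 0.096, VTC4 -0.087 to 0.046 and BNA1 -1.081 to 0.002. BAR1 had -0.399 to 0.023, ASG7 -0.67 to 0.469, STE6 -0.141 to 0.015, TRP1 -0.5 to 0.328 and HIS3 -0.456 to 0.249 there.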

Other observations

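The values for CAT2, VPS71, the small nucleolar RNAs, the sulfur genes, the NAD synthesis genes and the ribosomal DNA genes were looked up after the results were seen, as was the setting without the libraries numbered 1, and no explanation was tested here.

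Small nucleolar RNAs moved apart within their list. snR78 rose in spt6-R (1.895 ± 0.42), spt6-KK (2.06 ± 0.41), spt6-R,KK (2.82 ± 0.41), rpb1-FSP (1.92 ± 0.42) and rpb1-TPY,FSP (2.67 ± 0.41). snR77 rose in the same 5 strains, by 1.88 in spt6-R, 1.79 in spt6-KK, 2.40 ± 0.28 in spt6-R,KK, 1.67 in rpb1-FSP and 2.33 ± 0.28 in rpb1-TPY,FSP. snR33 fell in the same 5 strains, from -0.85 ± 0.20 in spt6-R to -1.73 ± 0.21 in rpb1-TPY,FSP. In rpb1-TPY none of these passed (snR78 0.59, snR77 -0.02, snR33 -0.44, each adjusted p = 1 by edgeR). The call of snR78 was lost in spt6-R without WT library 2 (adjusted p = 0.0762) or spt6-R library 3 (0.0537), and in rpb1-FSP without WT library 1 (0.0701) or 2 (0.118) or rpb1-FSP library 3 (0.11). That of snR33 was lost in spt6-R without WT library 2 (0.0982) or spt6-R library 3 (0.0703).

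Among sulfur assimilation genes MET3, the ATP sulfurylase gene, rose in spt6-R (1.63 ± 0.11), spt6-KK (1.37 ± 0.11), spt6-R,KK (1.31 ± 0.11), rpb1-FSP (0.91 ± 0.11) and rpb1-TPY,FSP (0.90 ± 0.11). MET10, a sulfite reductase gene, rose in both double mutants (1.77 ± 0.17 and 1.67 ± 0.17). MET2 fell in both (-1.25 and -1.33), with calls that were lost without WT library 2 (edgeR adjusted p = 0.179 and 0.125). The methionine and sulfur list was not called in spt6-R,KK. Among NAD synthesis genes, whose list was not called in either double mutant (camera adjusted p = 0.393 and 0.172), the kynurenine pathway genes BNA7 and BNA5 fell in both, BNA7 at -0.98 ± 0.19 and -0.95 ± 0.19 and BNA5 at -0.94 ± 0.31 and -1.60 ± 0.32. In spt6-R,KK the call of BNA5 was lost without WT library 1 (adjusted p = 0.0916) or spt6-R,KK library 2 (0.0945) or 3 (0.11), and BNA5 had -1.519 without spt6-R,KK library 1. BNA2 (0.43 and 0.40), BNA4 (-0.50 and -0.58) and BNA1 (0.38 and -0.30) did not pass. In spt6-R,KK BNA1 turned to -1.068 and passed without the libraries numbered 1 of both double mutants (adjusted p = 0.0258). With the libraries numbered 1 left out, 6 of 11 NAD synthesis genes fell and 1 rose in each double mutant (camera adjusted p = 0.0261 and 0.0533, adjusted p = 0.305 and 0.383 with an estimated correlation), and amino acid synthesis genes had medians of -0.11 and -0.10.

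CAT2 rose in both double mutants (1.64 and 1.54) and, with calls that were lost without WT library 1 or 2 and without 2 libraries of the strain, in rpb1-TPY (1.24; lost at adjusted p 0.0973 to 0.254), spt6-R (0.82, adjusted p = 0.0227; lost at 0.0554 to 0.0913) and spt6-KK (0.76, adjusted p = 0.0219; lost at 0.0604 to 0.109). Its neighbour VPS71 had 1.05 in rpb1-TPY (lost without WT library 1 or 2 or rpb1-TPY library 2 or 3, adjusted p 0.0617 to 0.254), 0.07 in spt6-R,KK and 0.20 in rpb1-TPY,FSP.

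Among 49 tested genes counted only over mid-gene regions, 1 rose and 3 fell in spt6-R, 2 rose and 6 fell in spt6-KK, 7 rose and 6 fell in spt6-R,KK, 0 rose and 3 fell in rpb1-TPY, 1 rose and 4 fell in rpb1-FSP, and 5 rose and 8 fell in rpb1-TPY,FSP (edgeR on mid-gene counts). The falls in spt6-R, rpb1-TPY and rpb1-FSP were all in ribosomal DNA (RDN25-1, RDN37-1, TAR1 and, in rpb1-FSP, RDN18-1), as were 4 of 6 in spt6-KK, 5 of 6 in spt6-R,KK and 5 of 8 in rpb1-TPY,FSP. Ribosomal RNA took 7.10% to 19.1% of the mid-gene counts in WT and 2.98% to 6.21% in the mutants. The libraries had been depleted of ribosomal RNA, so these counts are what depletion left. A difference in depletion between WT and the mutants cannot be told apart from a change in ribosomal DNA transcripts.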
